A study of Halanaerobium congolense with 13 samples.

How the data were processed

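The data describe RNA from biofilms of *Halanaerobium congolense* DSM 11287 on 7 coupon materials in 1 anaerobic biofilm reactor, at 20 °C, with a flow of 1 ml per min of a medium with 15% NaCl, 20 mM glucose and 20 mM thiosulfate, per the labels' protocols. Whole coupons were preserved and frozen, and RNA isolation, library construction and sequencing on a HiSeq instrument were done by a service laboratory, per the labels' protocols. There were 13 libraries: 2 each on apatite, basalt, feldspar, limestone, glass and polycarbonate, and 1 on stainless steel. Groups were taken from the labels.

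The submitters' processing notes name Bowtie2 2.2.9 and Cufflinks 2.2.1, without saying which step each served. The genome build and the strand setting are not given in the sources used here. The deposited table has the column layout of a pairwise Cuffdiff comparison per the file headers: for each of 21 pairs of surfaces, 2 FPKM values, a log2 fold change, a p-value, a q-value and a status. The FPKM values deposited by the authors pool the libraries of a surface, and the mean column of each surface equals the mean of its 6 pairwise values. The scale of a surface differed by comparison, from 88.7% to 109% of its mean by the median gene, so the authors' fold changes were taken within a comparison. The comparison of natural with manufactured surfaces, and FPKM values set side by side for the surfaces, used the mean columns. The log2 fold change deposited by the authors was checked to be the second surface over the first. The p-value and q-value were deposited by the authors; the table's flag of significance equals a q under 0.05 in all 21 comparisons. The q-values were adjusted by the authors over more genes than the table holds. Identity in percent, the bit score and the other alignment values of each match to a sporulation gene, per the file headers, came from a sequence search whose program is not given in the sources used here.

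The table holds 190 rows matched to 91 sporulation genes, with identities from 30.1% to 89.5%, under 40% for 133 rows. A match at this level gives a name and not a function. Of the rows, 28 had no expression values and 26 had values but were not tested by the authors, 24 of them listed at 0 on all surfaces. Among the 136 tested genes, 15 share a locus with another row, so that reads of neighbouring genes could be mixed, and genes of the same family could share reads. Coordinates are given on contigs as numbered in the table, counted from 1. Because the table was selected by similarity to sporulation genes, it says nothing about other genes, and totals cannot serve as depth. The values used here are not counts, so depth per library is unknown and no counting interval is given.

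The tests planned before the data were examined needed 1 value per library. The table gives 1 pooled value per surface and comparison, so the planned F test over surfaces, the contrasts of each surface with the mean of the others, the contrast of calcium minerals with silicates, the gene list tests on these contrasts and the similarity of duplicates could not be fitted. In their place the authors' own calls (q under 0.05) were counted. A gene was counted for a surface when it was called in the same direction in all 6 comparisons of that surface, and for calcium minerals when called in the same direction in all 4 comparisons of apatite and limestone with basalt and feldspar. The median of the 6 log2 fold changes describes its size. The overlap expected without any effect was simulated for 100000 genes with 6 comparisons that share the limestone libraries, and likewise for stainless steel with 1 library against 2, assuming the same spread per library on each surface.

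The comparison of natural with manufactured surfaces was fitted as planned, with 1 value per material, on log2(FPKM + 1) of the mean columns, in limma 3.58.1 (R 4.3.3) with a trended, robust variance, Benjamini-Hochberg adjustment and genes at 1 FPKM or more on at least 2 surfaces. The mean over duplicates was the authors', made on the FPKM scale and not on the planned log2 scale. Fold changes on this scale are understated for low genes. Gene lists, written before the data were examined by words of the annotation or gene names, were tested with camera where at least 5 members were tested, which left 6 of 34 lists: peptide and amino acid transport, two-component regulators, peptidoglycan and cell division, oxygen and redox stress, sporulation-related genes, and a list for Rnf and ATP synthase whose 12 matches were ytrE proteins. Limestone calls within these lists and within 8 function classes of the table were compared with the other tested genes by Fisher's exact test, two-sided, adjusted over 28 tests; this test replaced the planned one. Genes are not independent replicates in it. In profiles simulated for the natural and manufactured comparison with 136 genes, limma recovered 15 of 15 genes changed by 1 on the log2 scale and 15 of 15 changed by 2, with 1 false call, at a spread between surfaces of 0.14 on the log2 scale taken without limestone. That spread is narrower than in the real fit. With the spread of each gene within the classes, limestone included (median 0.25, highest 1.59 on the log2 scale), limma recovered 77.1% of genes changed by 1 and 95.3% of genes changed by 2 over 200 simulated profiles of 136 genes, with 1.26 false calls per profile. Each profile held 15 genes changed by each size, all in 1 direction. Recovery where only few genes change was not simulated and could be lower.

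Genes were named by a rule written before the data were examined: the 6 highest and 6 lowest by fold for a surface, the 10 with the smallest p where fewer than 10 pass between natural and manufactured surfaces, up to 4 members of lists with called members, and the 5 most abundant genes. The part of the rule for the F test could not be used, since the smallest p of the table is shared by many genes, and for surfaces with few calls the genes called in 3 or more comparisons were named instead, after their values were seen. Alternatives planned for the class comparison covered normalization, low-value filters, the pseudocount (0.1 and 10 in place of 1), the variance trend and leaving out each surface. Alternatives for the authors' calls were added after the data were seen, apart from the filter at a mean of 10 FPKM, and covered the threshold, the adjustment, a 2-fold minimum, shared loci, the number of comparisons needed and leaving out each comparison. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.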

Results

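RNA was sequenced from biofilms of *Halanaerobium congolense* DSM 11287, a salt-requiring anaerobic bacterium that reduces thiosulfate, grown for 8 weeks in 1 flow-through reactor on coupons of 7 materials. The labels class 4 materials as natural (apatite, basalt, feldspar and limestone, 8 libraries) and 3 as manufactured (glass, polycarbonate and stainless steel, 5 libraries). Each material had 2 libraries except stainless steel, which had 1. Since all coupons came from the same reactor run, the authors' p-values measure at most the spread between coupons, which may be technical. Stainless steel, with 1 library, has no such spread of its own. The p-values for natural against manufactured surfaces, with 1 value per material, measure the spread between materials in this 1 run. The deposited values are FPKM per surface, with replicates pooled by the authors, so no spread between libraries could be computed and the sequencing depth is unknown. The table covers 190 rows, each a protein of this organism matched to a known sporulation gene of another species, and not the whole transcriptome. Expression values were present for 162 rows, of which 136 were tested by the authors in all 21 pairs of surfaces. Gene names below are those of the best match, with a median identity of 35.6%, so several proteins carry the same name and each is given with its locus tag.

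Among these sporulation matches, the most abundant transcript by the mean over the 7 surfaces was matched to spoVT (BMY48_RS05575, contig 7, 35436 to 35690), with 42080 FPKM. The spoVT protein is a transcriptional regulator of late sporulation genes in *Bacillus*. The spoVT match was followed by spoVG (BMY48_RS11715) at 11205 FPKM and by a protein matched to the sporulation response regulator spo0A (BMY48_RS09990) at 10509 FPKM. The eag match BMY48_RS06240 and the sigma factor match sigH (BMY48_RS12355) had means of 8093 and 5820 FPKM. The eag match of the authors' deposited table ranged from 7476 FPKM on stainless steel to 9403 FPKM on limestone, and sigH from 5135 FPKM on glass to 6416 FPKM on apatite. The order of the means did not hold on limestone, where the spoVT match stood at 2806 FPKM, below eag and below sigH at 5697 FPKM.

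The first question was which of these genes differed among the surfaces. Per the authors' deposited table, 76 of the 136 tested genes (55.9%) had a q-value under 0.05 in at least 1 of the 21 comparisons. The differences lay mainly with limestone. The 6 comparisons with limestone held 309 calls, from 47 to 63 genes each, and the 15 comparisons without limestone held 73, with at most 24 in 1 comparison, per the authors' deposited table. Stainless steel, with its 1 library, took part in 44 of these 73; the 10 comparisons with neither surface held 29 calls, at most 14 in 1 comparison, in the authors' deposited table. Of those 15 comparisons, 5 had 0 calls in the authors' deposited table, made by a Cuffdiff-type test. They were apatite with polycarbonate, basalt with apatite, basalt with glass, basalt with polycarbonate, and feldspar with glass. At an unadjusted p under 0.05 these 5 held 0, 11, 4, 4 and 1 genes, respectively, in the authors' deposited table. Across genes, Spearman correlations of the log2 values lay between 0.919 and 0.945 for limestone with another surface and between 0.990 and 0.998 for pairs of other surfaces; genes are not independent replicates.

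**Figure D1:**
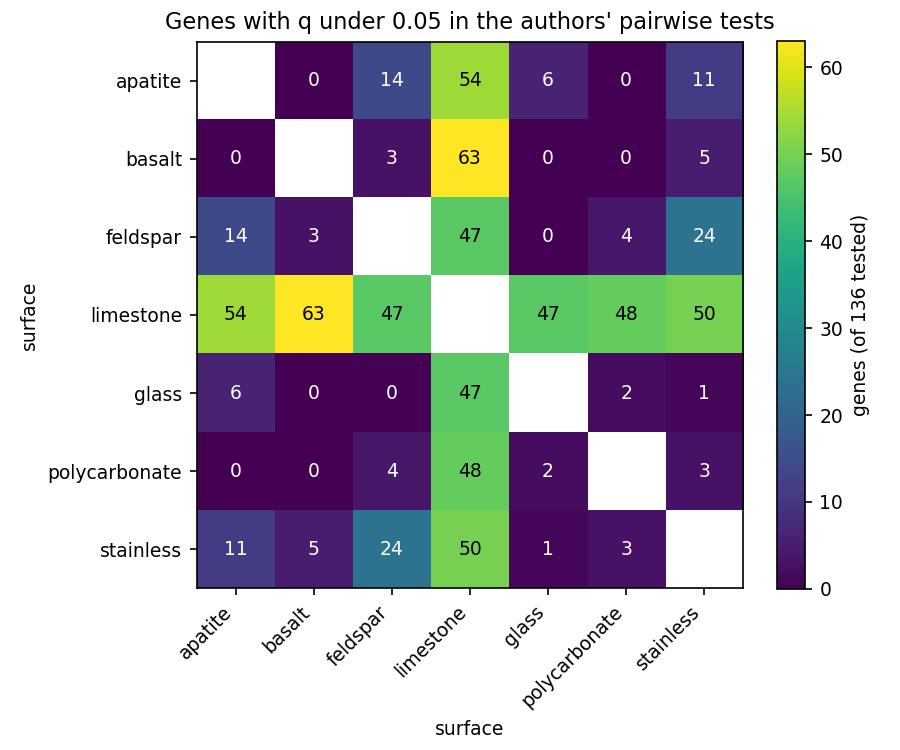
Number of genes with a q-value under 0.05 in each of the 21 pairwise tests in the authors' deposited table, out of 136 tested genes; both axes list the 7 surfaces and colour gives the number of genes. The limestone row and column hold 47 to 63 genes, and no other cell exceeds 24.

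On limestone some genes matched to sporulation regulators and sensor kinases were lower, and some matched to peptide transporter subunits higher, than on each of the other 6 surfaces. Of the tested genes, 31 were called by the authors' deposited table in the same direction in all 6 limestone comparisons, 14 of them higher and 17 lower on limestone. With unchanged genes and shared limestone libraries, a simulation gave 0.00952 such genes, and independent lists of the observed sizes would share 0.00441 higher and 0.00788 lower genes; part of the excess may come from the shared limestone libraries. The median over the 6 comparisons was at least 2-fold for 9 of the genes called higher and 16 of those called lower. With q under 0.01 the count was 19, and with at least 2-fold in each comparison it was 16.

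Among the genes lower on limestone, the spoVT match fell most. It stood in the authors' deposited table at 2806 FPKM on limestone and between 34296 and 64728 FPKM elsewhere, a median log2 fold change of -3.86 (largest q = 0.000464). The spoVG match, a regulator that affects cell division and sporulation in *Bacillus*, stood at 2343 FPKM on limestone and 9131 to 15836 FPKM elsewhere in the authors' deposited table, with a median log2 fold change of -2.32. Adjacent genes on contig 37 matched to the sensor kinase kinD (BMY48_RS13115, 3545 to 5041) and to spo0A (BMY48_RS13120, 5064 to 6572) had median log2 fold changes of -2.46 and -2.08 in the authors' deposited table. A further spo0A match (BMY48_RS08100) and ytkL (BMY48_RS07105) had medians of -2.06 and -1.91 in the authors' deposited table. BMY48_RS08100 shares its locus with a CD1579 match, so reads of both could be mixed. The abundant spo0A match BMY48_RS09990 fell by 1.45 on the log2 scale (largest q = 0.000864), per the authors' deposited table. The loci of spoVT and spoVG are short, 255 and 267 bp, and a dependence on locus length was not excluded for limestone, although across the tested genes the Spearman correlation of the median log2 fold change with locus length was -0.096. Of 2 spoVS matches with loci of 261 bp each, singled out after their values were seen, BMY48_RS04985 had a median log2 fold change of -1.57 and was called lower in all 6 comparisons, whereas BMY48_RS05955 had a median of 0.56 and was called higher in 2, per the authors' deposited table.

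The genes higher on limestone were led by members of a run of 4 neighbours on contig 19, all matched to subunits of ABC transporters for peptides at 34.0% to 49.4% identity. For these genes the authors' deposited table gave median log2 fold changes: its dppB (BMY48_RS10060, 6687 to 7625), oppC (BMY48_RS10055) and oppF (BMY48_RS10045, 3820 to 4800) matches had 1.98, 1.82 and 1.61, with a largest q of 0.000464. The remaining member of the run, an oppD match (BMY48_RS10050), had a median of 0.80 and was called higher in 5 of the 6 comparisons (largest q = 0.0622), per the authors' deposited table. The dppB match reached 410 FPKM on limestone against 98.3 to 176 FPKM elsewhere in the authors' deposited table. A second dppB match (BMY48_RS14020), a ytrE match (BMY48_RS00160, an ABC transporter ATPase that shares its locus with another ytrE match) and dppC (BMY48_RS02830) followed at 1.76, 1.49 and 1.43 in the authors' deposited table.

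**Figure D2:**
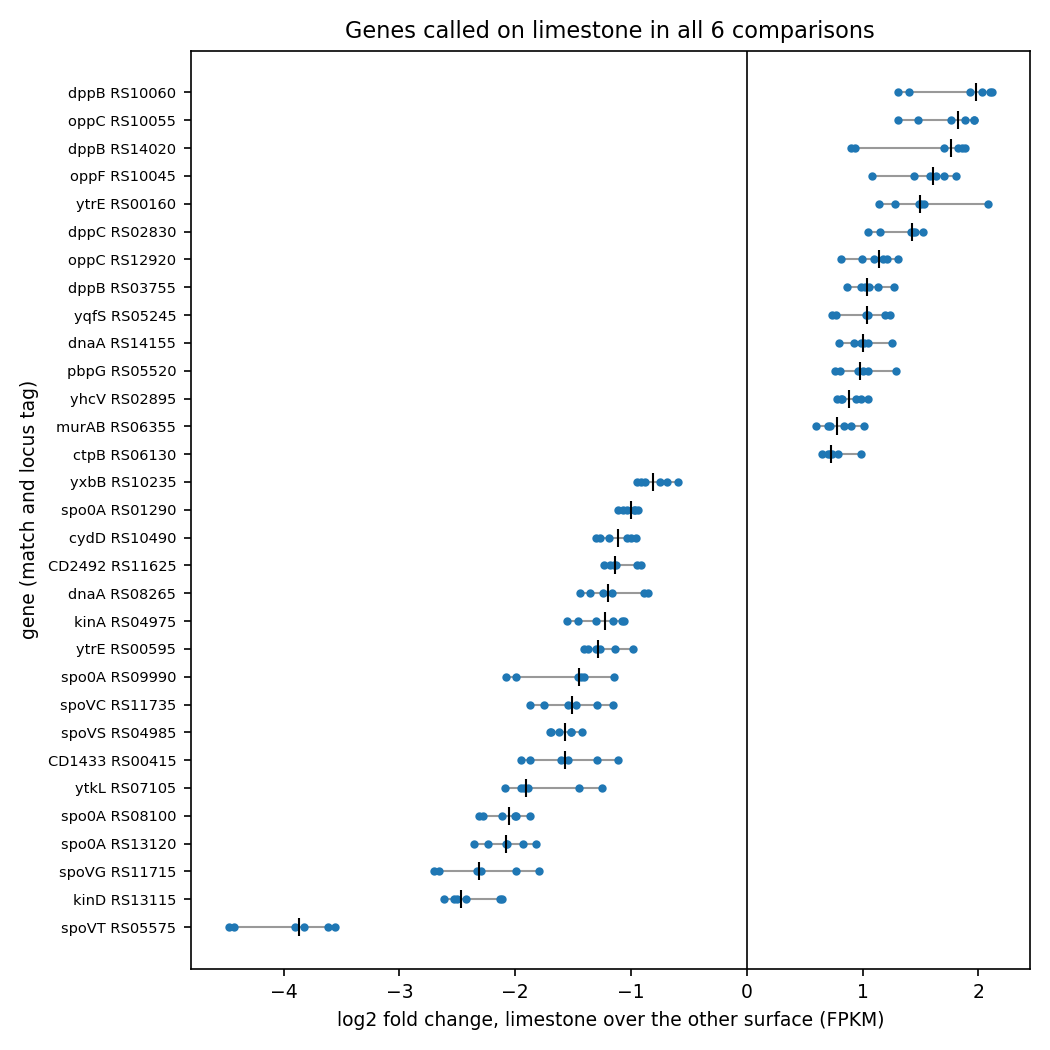
Log2 fold change of FPKM on limestone over each other surface, from the authors' deposited table, for the 31 genes called in the same direction in all 6 comparisons; each point is 1 comparison, the grey line spans the lowest and highest, and the black tick is the median. The medians run from -3.86 for spoVT to 1.98 for the dppB match BMY48_RS10060.

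Among the lists fixed before the data were examined, peptide and amino acid transport had 7 of 19 tested members called higher on limestone in all 6 comparisons, 0 called lower and 12 in neither group (Fisher's exact test, two-sided, adjusted p = 0.0112). Adjusted over the list alone, 8 members passed. The called members include the contig 19 genes BMY48_RS10060, BMY48_RS10055 and BMY48_RS10045 and dppC (BMY48_RS02830). Two-component regulators, matched to sensor kinases and response regulators, had 7 of 16 members called lower, 0 called higher and 9 in neither group (Fisher's exact test, two-sided, adjusted p = 0.0112, and 7 adjusted over the list alone). They include kinD (BMY48_RS13115) and the spo0A matches BMY48_RS13120, BMY48_RS09990 and BMY48_RS08100. Many members are neighbours on the genome. With only the first gene by position kept per run of neighbours, a choice made after the data were seen, neither list passed. Fisher's exact test gave adjusted p = 0.441 for peptide transport and 0.196 for the regulators. This choice dropped called members such as dppC (BMY48_RS02830) and spo0A (BMY48_RS08100) and made the lists smaller. The loss therefore cannot be assigned to neighbours alone.

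The other 4 fixed lists did not pass. The broad sporulation-related list had 5 of 57 members called higher and 11 called lower (adjusted p = 0.989 and 0.256, Fisher's exact test), with 5 and 10 adjusted over the list alone. Of 5 peptidoglycan and cell division members, 2 were called higher, pbpG (BMY48_RS05520) and murAB (BMY48_RS06355), at medians of 0.98 and 0.78 in the authors' deposited table (adjusted p = 0.289, Fisher's exact test). Of 5 oxygen and redox stress members, 1 was called lower, the CD1433 match BMY48_RS00415 at -1.57 in the authors' deposited table (adjusted p = 0.880, Fisher's exact test). The list written for Rnf and ATP synthase matched 12 ytrE proteins through the words of their annotation; these are ABC transporter ATPases and not ATP synthase subunits, and BMY48_RS00160 was called higher and BMY48_RS00595 lower (adjusted p = 1 for either direction, Fisher's exact test).

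On stainless steel the gene called most often was an oppB match (BMY48_RS12915, contig 35, 17688 to 18692), named for a permease subunit of a peptide transporter. The authors' deposited table gave 37.4 FPKM on stainless steel and 9.35 to 13.98 FPKM elsewhere, a median log2 fold change of 1.60, and the gene was called higher in all 6 comparisons (largest q = 0.0447). These comparisons share the 1 stainless library, and a simulation of unchanged genes with that sharing gave 0.00272 genes in all 6, from 2 of 100000 simulated genes. That value assumes the same spread per library on each surface and does not cover a property of the stainless library as a whole. How the authors' test set the spread of a surface with 1 library is not given in the sources used here. The oppB match was the only gene so called on stainless steel, and with the p-values adjusted over the table's tested genes alone the count was 0; at an unadjusted p under 0.05, 3 genes reached all 6 in the authors' deposited table. The ytlC match BMY48_RS11665 and the oppC match BMY48_RS07485 were called higher in 5 of the 6 comparisons, with medians of 2.12 and 1.05, and the spo0F match BMY48_RS03390 in 4, with a median of 1.55, per the authors' deposited table. Called in 3 were kinC (BMY48_RS03395) and ytrE (BMY48_RS12660) as higher and the lonB protease matches BMY48_RS03620 and BMY48_RS12410 as lower, per the authors' deposited table. With 1 library, stainless steel has no replicate of its own, and 10 of the 11 genes of lowest abundance, under 20 FPKM elsewhere, were higher on it than on the other surfaces apart from limestone. The oppB match, ytlC (BMY48_RS11665), oppC (BMY48_RS07485), spo0F (BMY48_RS03390) and kinC are among these 10, so their differences were not separated from a shift of low-abundance genes in this library.

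For apatite, basalt, feldspar, glass and polycarbonate, 0 genes were called in the same direction against all 6 other surfaces in the authors' deposited table, and 0 at an unadjusted p under 0.05. Genes called in 3 or more of the 6 comparisons, named here after their values were seen, were spoVG, CD1433 (BMY48_RS00415) and spo0A (BMY48_RS09990) as higher on apatite, and the dppB matches BMY48_RS10060 and BMY48_RS14020 and yloB (BMY48_RS10220) as lower on apatite, per the authors' deposited table. Both dppB matches were called higher on feldspar in 4 comparisons and lower in 1, that with limestone, ytkL (BMY48_RS07105) was called lower on feldspar in 3 and higher in 1, that with limestone, and spoVG higher on polycarbonate in 3, per the authors' deposited table. For each gene named for apatite, and for spoVG on polycarbonate, the comparison with limestone was among the 3. Basalt and glass had none in 3 or more. The direct comparison of feldspar with apatite held 14 calls in the authors' deposited table, 6 of them higher on feldspar and 8 higher on apatite.

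The labels also divide the surfaces into natural and manufactured. With each material as 1 replicate, 0 of 136 genes differed between the 4 natural and 3 manufactured surfaces (limma, adjusted p under 0.05), and 1 passed at an unadjusted p under 0.05. The smallest adjusted p was 0.856 (limma). The 10 genes with the smallest p, none of which passed, were all lower on natural surfaces on average. They were ytrE (BMY48_RS00710, log2 difference of -0.27, SE 0.10), spo0F (BMY48_RS03390, -0.83, SE 0.37), ytrE (BMY48_RS12660, -0.44), spo0F (BMY48_RS11620, -0.63), yknV (BMY48_RS08630, -0.43), uxaA (BMY48_RS07870, -0.28), oppC (BMY48_RS07485, -0.56), kinC (BMY48_RS03395, -0.60), yknV (BMY48_RS09000, -0.51) and cydD (BMY48_RS05105, -0.29). Without stainless steel, which has 1 library, 7 of these 10 differences moved by over 1.5 times: to -0.43 and -0.40 for the spo0F matches BMY48_RS03390 and BMY48_RS11620, -0.28 for ytrE (BMY48_RS12660), -0.22 for yknV (BMY48_RS08630), -0.18 for uxaA, -0.23 for oppC and -0.36 for kinC. Without limestone, 3 did so, to -0.39 for kinC, -0.29 for yknV (BMY48_RS09000) and -0.14 for cydD. Under quantile normalization ytrE (BMY48_RS12660), both yknV matches and uxaA changed sign, kinC and oppC came to -0.003 and -0.06, and the spo0F matches BMY48_RS03390 and BMY48_RS11620 shrank to -0.19 and -0.40. At a pseudocount of 10, 3 of the 10 differences also moved by over 1.5 times. The first gene had 53.5 ± 2.80 FPKM on natural surfaces (SD, n = 4) and 64.8 ± 2.11 FPKM on manufactured surfaces (SD, n = 3).

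Of the 6 fixed lists, 2 passed between natural and manufactured surfaces with a preset correlation of 0.01: peptide and amino acid transport as higher on natural surfaces and two-component regulators as lower (camera in limma, adjusted p = 0.0180 for both). With an estimated correlation neither passed (adjusted p = 0.597 for both, camera in limma), and without limestone the smallest adjusted p over the lists was 0.834 and peptide transport changed direction (camera in limma). Leaving out glass or polycarbonate also ended both calls, with smallest adjusted p values of 0.0678 and 0.0583 (camera in limma). No member of either list passed over all genes or adjusted over the list alone. The adjusted p was 0.986 for oxygen and redox stress, 0.523 for peptidoglycan and cell division, 0.172 for the list that matched ytrE proteins and 0.983 for the sporulation-related list (camera in limma).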

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

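The tests in this part were chosen after the results were seen, except the removal of abundance and length trends. For 25 named genes the 4 natural surfaces were searched for a value far from the other 3, where chance gives about 1.25. The cydD match BMY48_RS05105 stood at 72.5 FPKM on limestone and between 107 and 113 FPKM on apatite, basalt and feldspar.

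Genes on limestone differed from all 6 other surfaces in both directions. One scale factor for the limestone libraries would move all called genes 1 way, and 14 were higher while 17 were lower. If only 1 of the 2 limestone libraries differed, a mean could not fall below 0.5 of the other surfaces, provided the other library matched them; 11 of the genes called lower had all 6 log2 fold changes under -1, which argues against this for those 11. A length bias stayed open. The Spearman correlation of limestone fold change with locus length across genes was -0.096, a weak trend, but pairs of genes with locus lengths within 5% differed by 0.779 of the difference of all pairs, between the bounds set for either reading. With mean abundance on the other surfaces the Spearman correlation of limestone fold change was -0.187. A dependence on abundance was not tested for limestone and also stayed open. The material, and any shared handling or position of the limestone coupons, are confounded in this design and cannot be told apart.

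The 14 genes called between feldspar and apatite, which include spoVT and spoVG lower on feldspar and the contig 19 dppB, oppC and oppF matches higher, all had the same sign between limestone and basalt, a comparison that shares no library with the first. Over all tested genes 53.7% had the same sign, and 0.03% of 10000 random lists of 14 genes reached 14. That argues against chance only for genes that vary independently. Genes that vary together would agree or disagree as a set, so random lists of genes cannot exclude chance for the set. The 14 genes lie in 11 runs of neighbours. After a linear trend with abundance and length was removed from both comparisons, 14 of 14 kept the same sign, which argues against such a trend as the whole cause. One hypothesis is that these genes vary together along a common state of the biofilm that differs in degree between materials. This was not tested, and the material is not separated from handling.

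Genes of low abundance, under 20 FPKM on average over apatite, basalt, feldspar, glass and polycarbonate, were higher on stainless steel in 10 of 11 cases than on any of those 5 surfaces. Independent counting noise of 1 library would place values above and below alike. The 10 above are the pattern itself, found among 6 surfaces and both directions. If each gene is equally likely above or below all 5, as for a much noisier library, so uneven a count has a chance of 7.03% after that search. With equal noise on the 6 surfaces, the chance that a gene is highest on stainless steel would be lower, 16.7%, and was not used. The spread of this 1 library is unknown, so noise stayed open. The same count was 0 or 1 for each of the other 5 surfaces, although high stainless values leave little room for them. A constant background, such as DNA reads, would add the same FPKM to each gene, but 9 of the 11 genes had an excess above 2.97 FPKM, the whole stainless value of the exuR match, which argues against it as the whole cause. A property of this 1 library or of the steel coupon stays open, since stainless steel has no second library.

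Natural against manufactured surfaces gave 0 genes, so all 35 splits of the 7 surfaces into 4 and 3 gave as many by construction and the splits decide nothing for genes; the highest other value was 0. With the preset correlation, 27 of the 35 splits, the real split included, gave 2 passing gene lists, with a highest other value of 2. Which lists passed in the other splits was not recorded. Chance was therefore not excluded for the 2 lists of the real split, and with an estimated correlation 0 lists passed.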

How the results depend on the processing

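No paired analysis was possible because the table carries no replicate numbers. Leaving out single libraries, library-level class fits, the replicate block, and other scalings or pseudocounts of the authors' tests were not run, since they need values per library; depth is unknown and limits genes of low FPKM most. For the authors' calls all alternatives but the 10 FPKM filter were added after the data were seen. Of 158 counts under alternatives, 136 stayed within 1.5 times. Many of these counts were 0 in the main setting, such as those for basalt and glass. A stricter threshold or filter could not change them, so the share of unchanged counts says little about stability. The cause of the changes was not tested where fewer genes or comparisons do not give it by construction. With q under 0.01 the count was 19 for limestone, 0 for stainless steel, 36 calls over comparisons without limestone and 4 passing lists and classes in place of 2. With a 2-fold minimum, limestone had 16 genes, any comparison 46, the limestone comparisons 172 calls, the others 17, and 5 lists and classes passed. Called in at least 4 of 6 comparisons were 50 genes for limestone, 4 for stainless steel and 2 for feldspar. Adjusting over the table's genes left stainless steel with 0 genes, and over all comparisons together with 2 and 1 passing list. Leaving out each comparison gave 1 to 3 genes for stainless steel, 3 without glass. Keeping 1 gene per run of neighbours left 0 lists. Between natural and manufactured surfaces 0 genes passed in every alternative run, while the 2 lists became 0 without limestone, glass or polycarbonate, with an estimated correlation and with fry (range 0 to 2). Of 281 values for named genes and lists, 264 kept their direction and side of the threshold or, for limestone folds, moved by less than their SD over comparisons. Part of this was fixed in advance. The limestone genes were chosen as called in 1 direction in all 6 comparisons, so leaving out 1 comparison could not reverse their median. The 139 gene values between natural and manufactured surfaces had no call to lose. Two-component regulators lost their call when adjusted over all comparisons (adjusted p = 0.0606), as did both lists with 1 gene per run; of 32 values of these lists between natural and manufactured surfaces, 9 lost the threshold and 1, peptide transport without limestone, reversed (adjusted p = 0.834; 0.000596 to 0.834 over the surfaces left out). Sizes held less: 21 of 139 gene values between natural and manufactured surfaces moved by over 1.5 times or reversed, 8 under quantile normalization, 7 without stainless steel, 3 without limestone and 3 at pseudocount 10. The other reversals were 4 genes, none passing, under quantile normalization: ytrE BMY48_RS12660 (0.0152), yknV BMY48_RS08630 (0.123), uxaA BMY48_RS07870 (0.00933) and yknV BMY48_RS09000 (0.0470). All 31 limestone genes remained when adjusted over the table's genes, and 28 without shared loci.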

Other observations

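The tests in this part were chosen after the results were seen. Function classes given by the table, which share members with the fixed lists, did not pass adjustment on limestone: 7 of 22 initiation genes and 4 of 9 coat genes were called lower (Fisher's exact test, adjusted p = 0.0707 and 0.102), and 8 of 40 transport genes were called higher and 1 lower (adjusted p = 0.126 in either direction). The 7 initiation genes are the same 7 called lower in the list of two-component regulators. The transport genes called higher are those of the peptide transport list and the ytrE match BMY48_RS00160. In cortex genes 1 of 7 was called higher, in metabolism 3 of 17 higher and 1 lower, in replication 2 of 11 higher and 1 lower, in genes of unknown function 2 of 14 lower and in genes with no class 1 of 6 lower. Adjusted over the class alone, metabolism had 0 genes called in either direction and genes of unknown function 1 called lower, while the other classes kept their counts. The median limestone log2 fold change of the 22 initiation genes was -0.74, at percentile 0.07 among 10000 random lists matched on expression. The coat genes were at percentile 19.2 (median -0.36) and the transport genes at 99.2 (median 0.37). The random lists drew genes singly, although members of a class can vary together, so these percentiles cannot exclude chance for a class. They were not adjusted for the number of lists. In replication, singled out after the values were seen, the dnaA match BMY48_RS14155 was higher (median 1.00) and the dnaA match BMY48_RS08265 lower (median -1.20) in the authors' deposited table.

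Apatite and limestone, both calcium minerals, were set against basalt and feldspar. Within the authors' deposited table no gene was called in the same direction in all 4 comparisons of apatite and limestone with basalt and feldspar by its Cuffdiff-type test, a count of 0 that was fixed by basalt with apatite, which held 0 calls. At an unadjusted p under 0.05 the count was also 0, while 54 genes were called between apatite and limestone. A hypothesis that calcium-containing minerals raise the yloB matches, named for a calcium-transporting ATPase, was tested on both tested genes. BMY48_RS10220 was called lower on apatite than on feldspar (log2 fold change -0.78, q = 0.00126) in the authors' deposited table, and did not pass against basalt (-0.41, q = 0.421). The call goes against the hypothesis for this gene only if feldspar held less calcium than apatite. The labels do not give the composition of the coupons. For BMY48_RS12240 apatite differed by -0.16 from feldspar (q = 0.623) and by -0.05 from basalt (q = 0.996) in the authors' deposited table, which leaves the hypothesis open for this gene. On limestone, the other calcium mineral, BMY48_RS12240 was called higher than on basalt (0.82, q = 0.00277) and feldspar (0.73, q = 0.0117), and BMY48_RS10220 higher than on basalt (0.76, q = 0.0112) but not feldspar (0.40, q = 0.232), in the authors' deposited table; limestone differed for many genes, so calcium is not separated from its other properties there. BMY48_RS10220 stood at 401 FPKM on apatite, 528 on basalt, 668 on feldspar and 850 on limestone, and BMY48_RS12240 at 62.7, 64.4, 67.8 and 108, in the authors' deposited table. Reads shared within this family were not excluded.

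Of 24 genes listed at 0 on all surfaces, 7 lay next to another such gene, on 2 contigs, and the others did not. Of 34 neighbouring pairs 5 were both listed at 0, 1 of them on a shared locus, against a median of 1 in shuffles, and 99.97% of shuffles gave fewer; most of these pairs lie in a single run on contig 2. On contig 21 all 4 rows and on contig 2 a run of 5 of 8 rows were listed at 0, whereas the yloB match BMY48_RS12235 at 0 adjoins the expressed BMY48_RS12240. For the runs, a candidate explanation is that segments of the reference are missing from the sequenced culture or were not counted; neither was tested.

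Neighbouring genes on separate loci were compared for their limestone fold change. Their median absolute difference was 0.60 on the log2 scale over 20 pairs against 0.78 in shuffles, and 83.0% of shuffles gave a larger value, short of the 95% set for a shared change of neighbours, so this stayed open; 17 of 20 pairs had the same sign.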
